A study of Homo sapiens with 8 samples.

How the data were processed

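MicroRNAs were measured by real-time PCR in lungs of mice that carried a human tumour. The tumour line was MDA-MB-435 with a GFP marker, a human line first described as breast cancer and now classed with melanoma lines. Per the labels' protocols, total RNA came from whole lungs of 4 animals with few lung metastases (oligometastatic, injected by tail vein with L1 cells) and 4 animals with many (polymetastatic, injected with the L1Mic derivative). Each extract therefore holds mouse and human RNA. Per the labels' protocols, replicate portions of each RNA were pooled before reverse transcription with human stem-loop primers, the cDNA was pre-amplified, and a TaqMan MicroRNA Array A card was run on a 7900HT instrument. The assays are designed on human sequences, and many mature microRNAs are identical in mouse, so an assay cannot in general tell the species apart.

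The deposited files hold 1 card per sample, with 384 wells and a cycle threshold (Ct) per well. A lower Ct means more template, and 1 cycle corresponds to about a factor of 2. Per the file headers, the baseline was set automatically and the threshold by hand at 0.3. The Ct values are not normalised, and whether the authors normalised them later is not given in the sources used here. Each card has 377 human miRNA assays, MammU6 in 4 wells, RNU44, RNU48 and ath-miR159a, a plant miRNA that serves as a negative control. The names are those of the assays, with the species prefix left off. The 4 MammU6 wells of a card had an SD of 0.0224 to 0.149 cycles and were averaged. No other assay was repeated on a card. The smallest median difference in Ct between any pair of samples, over 144 assays, was 0.334 cycles, so no card was taken for a copy of another.

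An assay counted as detected at a Ct of 35 or lower. Undetermined wells and wells above 35 were set to 35 before scaling, so differences that involve such wells are compressed. The log2 relative amount of a miRNA was the sample's mean Ct over the 144 miRNAs detected in all 8 samples minus the Ct of the miRNA. A miRNA was tested when it was detected in at least 3 samples of at least 1 group, which left 175. The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with Benjamini-Hochberg adjustment over the 175 miRNAs and a threshold of 0.05. Intervals for differences are limma's 95% intervals. A difference is always polymetastatic minus oligometastatic. The samples of a group are separate lungs per the labels, and no batch is named there. The design text speaks of 3 oligometastatic and 4 polymetastatic cell lines from 7 animals, whereas the sample labels describe 4 lungs of each kind, so the labels hold 1 oligometastatic sample more. The sample labels were followed, and which sample is the additional one is not given in the sources used here.

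Single values were compared with a two-sided exact permutation test over the 70 relabellings of the 8 samples. Its smallest possible p is 0.0286. The human snoRNA signal was defined as the Ct of MammU6, whose target is shared by mammals, minus the mean Ct of RNU44 and RNU48, whose assays are designed on human small nucleolar RNAs. It is a rough index of the human RNA in an extract and is not calibrated in cells. How far both assays also amplify the mouse counterparts is not known here, so a fold in this signal is not a fold in human RNA. Separation of the groups was the mean distance between samples of different groups minus that within groups, the distance being 1 minus Pearson's r over the tested miRNAs, with an exact test over the 35 splits into 4 and 4.

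Of 22 miRNA lists fixed before the data were examined, 17 had at least 2 tested members and were tested with limma's fry, which asks whether a list moves on balance one way and does not compare it with other miRNAs. Its p was adjusted over the 17 lists. The lists cover host cell types, human tumour cells, proliferation and other families, and miRNAs with a reputation in metastasis. The rule for named miRNAs was fixed at the same time. It takes the 12 greatest differences per direction among miRNAs past the threshold with no overlap of the groups. With fewer than 10 such miRNAs, the 10 with the smallest p are given as values. It adds all tested members of the miR-200, endothelium, melanocyte, hypoxia and erythroid lists, up to 4 of the most abundant members of any other list, and the control assays.

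Alternatives fixed at the same time were scaling to MammU6 or to RNU44 and RNU48, quantile normalisation, Ct limits of 32 and 38, undetected wells left missing, other detection filters, the human snoRNA signal as a covariate, the replicate number as a block, array weights, other list tests, other forms of the human snoRNA signal and leaving out each sample in turn. The test was tried on simulated data before use, with the residual spread of the 175 miRNAs and 20 miRNAs changed at each size. It recovered 38.0% of the changes of 2-fold, 72.4% of those of 4-fold and 88.7% of those of 8-fold, and 3.63% of its calls were false. The simulated miRNAs varied independently, whereas 1 principal component held 77.7% of the variance of the real ones, so these rates do not carry over to the lungs. The precision is limited by 4 lungs per group and a median within-group SD of 0.61 on the log2 scale. It differs between miRNAs, with a standard error of 0.42 at the median and 1.46 for miR-155.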

Results

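The 8 cards came from lungs of 4 oligometastatic and 4 polymetastatic animals. Between 43.0% and 48.5% of the 377 miRNA assays were detected per card. Across the cards, 204 miRNAs were detected at least once, 144 in all 8 samples and 173 in none. The number detected was 171 ± 7.85 (SD, n = 4) in oligometastatic and 175 ± 5.32 (SD, n = 4) in polymetastatic lungs, a difference of 4.75 assays with a two-sided exact permutation p of 0.400. The plant control ath-miR159a was undetermined on every card. MicroRNAs of host tissue were abundant: miR-126, a miRNA of endothelial cells, had a log2 relative amount of 9.91 ± 0.24 (SD, n = 4) in oligometastatic lungs, and the myeloid miR-223 had 6.18 ± 0.32 (SD, n = 4).

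The first question was how much human RNA the lungs of each group held. RNU48, a human small nucleolar RNA, had a Ct of 22.2, 31.1, 26.5 and 32.1 in oligometastatic replicates 1 to 4 and of 25.4, 23.7, 27.6 and 23.7 in polymetastatic replicates 1 to 4. RNU44 followed the same order of samples within the oligometastatic group, with Ct values of 25.4, 34.2, 28.6 and 35.6, and lay between 26.0 and 29.7 in the polymetastatic group. MammU6, the control shared by both species, lay between 16.9 and 19.4 on all cards. The human snoRNA signal was -11.61 ± 3.92 cycles (SD, n = 4) in oligometastatic and -7.96 ± 1.79 cycles (SD, n = 4) in polymetastatic lungs. The difference was 3.65 cycles, about 12.5-fold in snoRNA signal, and did not exceed the spread between lungs (two-sided exact permutation p = 0.200). Oligometastatic replicate 1, at -6.90, lay among the polymetastatic samples, and polymetastatic replicate 3, at -10.58, lay near oligometastatic replicate 3, at -10.07. The card of oligometastatic replicate 1 has a number from another series than the other 7. Among those 7 the difference was 5.22 cycles (exact permutation p = 0.0857), and a series with 1 card gives no value of its own. Without oligometastatic replicate 4 instead, whose RNU44 Ct lies above 35, the difference was 2.28 cycles (exact permutation p = 0.314).

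**Figure D1:**
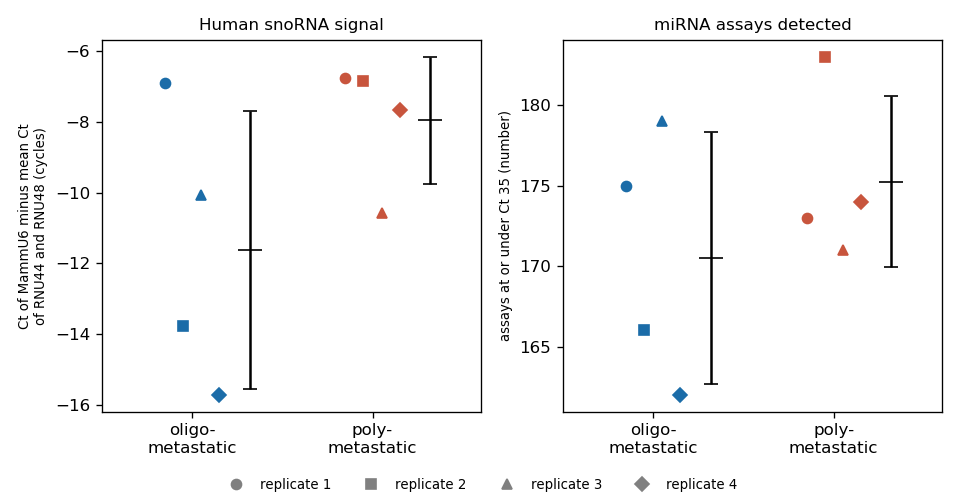
Human snoRNA signal in cycles (left) and number of miRNA assays at or under Ct 35 (right) for each lung, with the mean and SD of each group of 4 beside the points. The signal runs from -15.70 to -6.90 in oligometastatic and from -10.58 to -6.76 in polymetastatic samples, so the groups overlap.

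The main comparison asked which miRNAs differ between the lungs of the 2 kinds of animal. No miRNA passed: limma called 0 of 175 higher and 0 lower in polymetastatic lungs, the smallest adjusted p was 0.905, and 3 had an unadjusted p under 0.05, where 8.75 would be expected by chance. The miRNAs with the smallest p are given here as values. The log2 difference was -0.52 for miR-185 (95% interval -1.01 to -0.03), 0.82 for miR-671-3p (0.05 to 1.59) and -0.97 for miR-379 (-1.91 to -0.02), a member of the imprinted DLK1-DIO3 cluster. It was 0.98 for miR-221, -0.47 for miR-24, 0.65 for miR-21, -0.67 for miR-127-3p, -0.63 for miR-491-5p and -0.57 for miR-542-3p. The greatest of these 10 was miR-155, a miRNA of activated lymphocytes and of several tumours, at 2.99 (-0.37 to 6.35), with amounts of -2.70 ± 2.97 (SD, n = 4) in oligometastatic and 0.29 ± 1.56 (SD, n = 4) in polymetastatic lungs. Its highest oligometastatic value, 1.40, was in replicate 1, the lung of that group with the highest human snoRNA signal. The groups did not overlap for 3 miRNAs, 1.71% of those tested against 2.86% by chance; these were miR-185, miR-24 and miR-374b, all lower in polymetastatic lungs, the last of them named after its values were seen. Array weights, which gave oligometastatic replicate 1 a weight of 0.129, turned the counts to 21 higher and 3 lower, including miR-155, miR-204, miR-182 and miR-509-5p among the higher and miR-195 among the lower. Without oligometastatic replicate 1, limma called 0 miRNAs, with 43 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0819.

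MicroRNAs of the miR-200 family, which restrain the epithelial-to-mesenchymal transition and mark epithelium, were given a test of their own because they are known from work on this xenograft model. The 4 detected members, miR-200a, miR-200b, miR-200c and miR-141, were detected in all 8 samples, and miR-429 in none. Their mean log2 relative amount was 1.95 ± 0.42 (SD, n = 4) in oligometastatic and 1.70 ± 0.43 (SD, n = 4) in polymetastatic lungs. The difference of -0.25 did not pass the threshold of 0.05 (exact permutation p = 0.486). The difference turned positive, to 0.05, when the data were scaled to MammU6, which moves every miRNA by 0.30. With the human snoRNA signal as a covariate the difference was 0.17. It was -0.45 without oligometastatic replicate 1 and -0.46 without polymetastatic replicate 3 (exact permutation p = 0.143 for each), and -0.57 with array weights. Relative to the median of all miRNAs the difference was -0.13 under both the global mean and MammU6. The members had differences of -0.31 for miR-200a, -0.34 for miR-200b, -0.16 for miR-200c (-0.85 to 0.53) and -0.18 for miR-141. Their fry test gave an adjusted p of 0.863 with limma, and 0 of the 4 passed when adjusted over the list alone. In polymetastatic replicate 3, which had the lowest human snoRNA signal of its group, the family mean was 2.35, against 1.44 to 1.52 in the other 3.

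**Figure D2:**
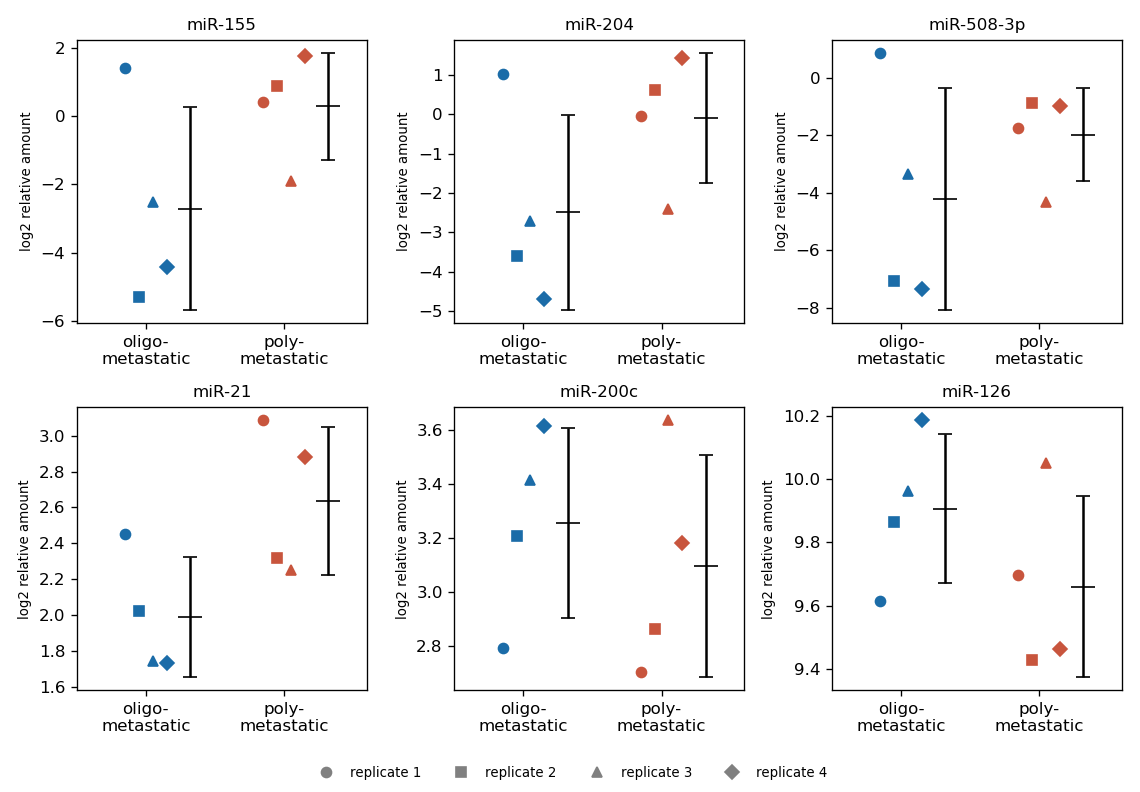
Log2 relative amounts of miR-155, miR-204, miR-508-3p, miR-21, miR-200c and miR-126 in each lung, with the mean and SD of each group of 4 beside the points and a separate vertical scale per miRNA. For miR-155, miR-204 and miR-508-3p, oligometastatic replicate 1 (circle) lies above the other oligometastatic samples and polymetastatic replicate 3 (triangle) below the other polymetastatic samples; miR-508-3p was not detected in oligometastatic replicates 2 and 4, whose points stand at the detection limit.

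Next, the miRNAs of human tumour cells were compared. In the primate cluster on the X chromosome from miR-506 to miR-514, 3 of 8 assays were tested, and all 3 had positive differences with wide intervals. The log2 difference was 2.25 for miR-508-3p (-1.93 to 6.43), 1.75 for miR-509-5p and 0.42 for miR-506, and the list had a fry adjusted p of 0.863 with limma. miR-508-3p was detected in 2 of 4 oligometastatic and 4 of 4 polymetastatic lungs, so its oligometastatic mean of -4.23 ± 3.86 (SD, n = 4) rests in part on the detection limit. Of the oligometastatic lungs, miR-509-5p was detected in replicates 1 and 3 and miR-506 in replicate 1 only. Their means rest on the limit too, and without replicate 1 the oligometastatic mean of miR-506 rests on it alone. Without oligometastatic replicate 1 the differences were 3.96 for miR-508-3p (limma adjusted p = 0.122), 3.47 for miR-509-5p (adjusted p = 0.0819) and 1.45 for miR-506 (adjusted p = 0.167), and the list had a fry adjusted p of 0.195. Of the melanocyte lineage, miR-204 had a difference of 2.40 (-0.60 to 5.40), and of 3.58 without oligometastatic replicate 1 (limma adjusted p = 0.0819). Its partner miR-211 was detected in oligometastatic replicates 1 and 3, at Ct 28.7 and 32.2, and in no polymetastatic sample, and was not tested. Of the 35 assays of the primate cluster around miR-515 to miR-527, 0 were tested and 1 was detected in any sample. This was miR-518f, at Ct 34.1 and 34.0 in oligometastatic replicates 3 and 4, near the limit, and above 35 in all other samples. None of the 3 assays from miR-371 to miR-373, and none of the 5 for liver, neuron and pancreas, was detected. The human snoRNA signal differed between the same lungs by 3.65 cycles, as given above.

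No miRNA or list of host cell types passed the threshold. All 3 endothelial miRNAs had negative differences, of -0.25 for miR-126 (-0.82 to 0.32), -0.48 for miR-218 and -0.12 for miR-10a, with a list adjusted p of 0.673 by limma's fry. In the smooth muscle and fibroblast list, 4 of 6 were negative (adjusted p = 0.864 by fry in limma), with -0.23 for miR-145, -0.51 for miR-143, -0.25 for miR-199a-3p and 0.07 for miR-214. The 3 striated muscle miRNAs had the most negative values of the host lists, -1.31 for miR-133a (-3.08 to 0.47), -1.16 for miR-1 and -1.01 for miR-133b, with an adjusted p of 0.673. The 3 miRNAs of ciliated airway cells were also negative, at -0.13 for miR-34c-5p, -0.80 for miR-449a and -0.54 for miR-449b (adjusted p = 0.673). Among 7 leukocyte miRNAs, 2 were positive and 5 negative, with 0.49 for miR-223, -0.49 for miR-146a, -0.39 for miR-150 and -0.08 for miR-142-3p. The list's mean of 0.28, carried by miR-155, and its median of -0.08 had opposite signs, and fry gave an adjusted p of 0.997. The erythroid miR-451, miR-486-5p and miR-486-3p had differences of -0.14, -0.15 and 0.01 (adjusted p = 0.979). The median difference over all 175 miRNAs was -0.12, and it was 0.17 after scaling to MammU6 and -3.47 after scaling to RNU44 and RNU48. These scalings shift every miRNA alike, MammU6 by 0.30. Without oligometastatic replicate 1 the endothelial differences were -0.34 for miR-126, -0.63 for miR-218 and -0.51 for miR-10a, with a list adjusted p of 0.195 by limma's fry. Members of other host lists moved as well, to -0.57 for miR-145, -0.60 for miR-199a-3p, -0.55 for miR-34c-5p and -0.48 for miR-451. Signs turned for miR-146a, to 0.18, miR-214, to -0.12, and miR-486-3p, to -0.19.

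Families linked to growth and metastasis were compared last. No list moved: 0 of the 17 passed fry in limma after adjustment, 1 had an unadjusted p under 0.05, and camera with an estimated correlation and the permutation of list means each gave 0 of 17 before and after adjustment. The list with the smallest p was that of miRNAs with a reputation for promoting metastasis, with 4 of 6 tested members positive and an adjusted p of 0.479 (0.512 with an estimated correlation). Its members include miR-155 and miR-21, named above, miR-214, and miR-103 at -0.36. The list of miRNAs reputed to restrain metastasis had 3 of 7 positive (adjusted p = 0.997), with 0.46 for miR-146b-5p and -0.23 for miR-31. In the cluster of miR-182, miR-183 and miR-96 all 3 were positive, at 1.54 for miR-182 (-0.42 to 3.51), 0.15 for miR-183 and 0.58 for miR-96 (adjusted p = 0.647). Of the proliferation-linked miR-17 cluster and its paralogs, 8 of 12 were positive (adjusted p = 0.864), with 0.15 for miR-17, 0.30 for miR-106a, -0.06 for miR-19b and 0.29 for miR-20a. The let-7 family had 2 of 8 positive (adjusted p = 0.997), with -0.18 for let-7b, -0.16 for let-7g, 0.22 for let-7e and -0.02 for let-7c. The miR-15/16 family had 2 of 4 positive, with -0.14 for miR-16, -0.44 for miR-195, 0.16 for miR-15b and 0.07 for miR-15a, and the miR-29 family 1 of 3, with -0.15 for miR-29a, -0.18 for miR-29c and 0.12 for miR-29b (adjusted p = 0.864 for each list). Both members of the pair of miR-221 and miR-222 were positive, miR-222 at 0.07 (adjusted p = 0.673). The DLK1-DIO3 cluster had 5 of 6 tested members negative (adjusted p = 0.647), with -0.24 for miR-494 and 0.53 for miR-411, which was positive. That positive sign rests on oligometastatic replicate 4, where miR-411 was not detected and stands at the limit, at -7.37. The other oligometastatic lungs had -3.73 to -1.49. Over determined wells the mean Ct of miR-411 was 30.5 in oligometastatic and 31.1 in polymetastatic lungs, which is less in the latter. The hypoxia miRNA miR-210 had a difference of -0.65 (-2.36 to 1.06), which rested on oligometastatic replicate 1, at -0.21 against -3.15 to -2.32 in the other 3 of its group, and was 0.01 without it. Leaving out that lung also moved members of the let-7 list, to -0.96 for let-7b, -0.45 for let-7g, -0.72 for let-7c and -0.13 for let-7e (list adjusted p = 0.277 by fry in limma), and of the miR-17 list, to 0.58 for miR-17, 0.86 for miR-106a and 0.41 for miR-19b (list adjusted p = 0.277). In other lists the same step gave 2.35 for miR-182, 0.40 for miR-222, 1.32 for miR-411, -0.49 for miR-494, -0.38 for miR-29c and -0.01 for miR-29b. In each of these lists 0 members passed with all 8 samples, over all miRNAs or adjusted over the list alone.

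The last comparison asked whether lungs of one group resembled each other more than lungs of the other. The mean distance was 0.0734 between groups and 0.0721 within groups, and 12 of the 35 splits gave a separation as large as that of the real groups (exact p = 0.343). After subtracting each miRNA's mean, 5 of the 8 samples correlated best with a sample of the other group. Oligometastatic replicate 1 had a mean correlation of -0.80 with its own group and 0.22 with the polymetastatic samples, and polymetastatic replicate 3 had -0.62 with its own group and 0.33 with the oligometastatic samples. Without oligometastatic replicate 1 the separation was 0.0381 (exact p = 0.0571).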

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

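All tests of explanations in this part were chosen after the values had been seen. In 18 of 164 comparisons of 4 samples, 1 sample stood apart from the other 3 by more than the 95% limit of Dixon's test, where about 1 in 20, here 8.20, would be expected by chance. Of these, 14 concern oligometastatic replicate 1.

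In oligometastatic replicate 1, the list means that stood apart were endothelium at 3.18 (others 4.01 to 4.13), leukocyte at 2.65 (1.76 to 1.91) and the miR-29 family at 2.80 (3.23 to 3.28). The leukocyte members did not move together. In that lung miR-155, at 1.40 (others -5.29 to -2.50), and miR-146a, at 8.25 (5.33 to 5.96), were the highest of the group. There miR-223, at 5.90 (5.98 to 6.61), and miR-142-5p, at -4.86 (-4.65 to -3.53), were the lowest. Among single miRNAs of that lung, miR-127-3p had a log2 relative amount of -2.09, miR-200a 1.53, miR-141 -1.22, miR-10a -0.70, miR-143 3.06, miR-199a-3p 2.08, let-7e 1.40, miR-506 -3.30, miR-106a 6.82, miR-19b 5.94 and miR-222 6.97. The first and the last 4 of these lay above the other oligometastatic lungs; miR-200a, miR-141, miR-10a, miR-143, miR-199a-3p and let-7e lay below them.

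The remaining samples apart were in the polymetastatic group. The miR-200 family mean of replicate 3 was 2.35, above the others. In replicate 4 the DLK1-DIO3 list mean was -4.94, below the others, and miR-223 was 7.68, above them. In replicate 2, miR-31 was 1.26, below the others.

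The card of oligometastatic replicate 1 carries a number of another series. The lung's deviation from the other 3 of its group was compared with slopes on the human snoRNA signal among the 4 polymetastatic samples. Across 174 miRNAs, which are not independent replicates, the Pearson r was 0.805 (95% interval 0.746 to 0.852). This argues against a card effect with a pattern of its own as the whole cause. A card effect on the same miRNAs is not excluded, as the lung's signal was read on that card. The slopes also rest largely on polymetastatic replicate 3, at a signal of -10.58 against -7.66 to -6.76 in the others. More human tumour RNA in oligometastatic replicate 1 may be the source, as its signal lay 3.17 cycles above the next of its group. That gap is less than the range of the polymetastatic group, 3.82, which leaves this open. The comparison rests on MammU6 as the reference. Of all samples, this lung had the lowest RNU44 and RNU48 Ct, 25.4 and 22.2. It also had the highest mean Ct of assays detected on all cards, 28.25. With that mean in place of MammU6, its signal would therefore be the highest of all samples. An exchange of labels with a polymetastatic lung cannot be told apart from more human tumour RNA in this lung. In all, 5 samples correlated best with a sample of the other group. Each of these best matches involved oligometastatic replicate 1 or polymetastatic replicate 3. With the labels of that 1 pair exchanged, every sample would correlate best with a sample of its own group. The split that exchanges this lung with polymetastatic replicate 3 gave 49 miRNAs and 6 lists, the only one of the 35 splits with miRNAs past the threshold, and it also puts the 4 samples with the highest human snoRNA signal together. A single miRNA of the melanocyte lineage, miR-211, was at Ct 28.7 in this lung and 32.2 in oligometastatic replicate 3. It was undetermined in oligometastatic replicates 2 and 4, and undetermined or above 35 in all 4 polymetastatic lungs (38.4 in replicate 3). Singled out after its values were seen and detected in 2 lungs only, it cannot decide for or against an exchange.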

How the results depend on the processing

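Of the counts of miRNAs and lists that differ between the groups, all were 0 under every alternative, except that array weights gave 21 miRNAs higher and 3 lower. Leaving out each sample in turn gave 0 calls each time (lowest and highest 0). The miR-200 difference was -0.46 to -0.15 with 1 sample left out and past the threshold under no alternative with a test. It was 0.0480 scaled to MammU6 and 0.168 with the human snoRNA signal as a covariate, against -0.57 with array weights and -3.60 scaled to RNU44 and RNU48, a setting that shifts the median of all miRNAs to -3.47. Both scalings shift every miRNA alike, MammU6 by 0.30, so their changes are not particular to the family. The cause of the changes with the covariate and with array weights was not tested. The human snoRNA difference ranged from 2.28 to 5.22 cycles with 1 sample left out, and the difference in detected assays from 1.92 to 7.58. Separation was -0.0150 to 0.0381 with 1 sample left out, and turned negative without oligometastatic replicate 2 (-0.000491) or 4 (-0.000473) and without polymetastatic replicate 1 (-0.00874), 2 (-0.0103) or 4 (-0.0150); the cause was not tested. Of 1174 values of the 63 named miRNAs under alternatives, 144 changed sign, none of them past the threshold on either side; 19 of these came from scaling to MammU6 and 24 from scaling to RNU44 and RNU48, which shift every miRNA alike. Of the 1174, 5 passed the threshold, all with array weights.

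The replicate number as a block gave 0 miRNAs in each direction (2 at an unadjusted p under 0.05), 0 lists, a miR-200 difference of -0.25 and a human snoRNA difference of 3.65. The numbers do not pair the samples: deviations of same-numbered samples correlated at -0.19, -0.55, 0.48 and -0.57, and not every sample correlated best with its own number.

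Added after seeing the data, the number of miRNAs that rise with the human snoRNA signal (19) was 30 with the global mean in place of MammU6 in the signal and 10 among miRNAs detected in all 8 samples. The number that fall (4) was 22 and 0 in those settings, 2 with the group as a term, 1 without oligometastatic replicate 1, 0 scaled to MammU6 and 16 with quantile normalisation. Fewer miRNAs (144) are tested in the detected-in-all setting; the cause of the others was not tested. Signals near the Ct limit of 35 limit what can be measured for miRNAs such as miR-506.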

Other observations

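The relations in this part were examined after the data had been seen, so they are hypotheses. Across the 8 samples, limma fitted the log2 relative amount of each miRNA on the human snoRNA signal, whichever group the lung belonged to. At an adjusted p under 0.05, 19 of 175 miRNAs rose with the signal and 4 fell, and with the group as a term 18 rose and 2 fell, 17 and 2 of them shared. With the global mean in place of MammU6 in the signal 30 rose and 22 fell, and among miRNAs detected in all 8 samples 10 rose and 0 fell. Per cycle of signal, miR-508-3p of the primate X-linked cluster rose by 0.84 ± 0.09 (SE; limma adjusted p = 0.000647), miR-9, best known from the nervous system, by 0.61 ± 0.07, miR-20b by 0.70 ± 0.09, miR-374a by 0.69 ± 0.09 and miR-155 by 0.74 ± 0.10. miR-204, 1 of 2 miRNAs of the melanocyte lineage on the card, rose by 0.64 ± 0.08, and miR-193b, miR-135b, miR-182 and miR-138 by 0.59, 0.53, 0.40 and 0.50. The falling miRNAs were miR-450a, miR-489, miR-674 and the smooth muscle miR-145 (-0.18 ± 0.05 per cycle). Scaled to MammU6, 21 rose and 0 fell past the threshold. The 4 falling slopes were then steeper but had larger errors, as for miR-145 at -0.26 ± 0.11 (limma adjusted p = 0.162), and with quantile normalisation 16 fell. Without oligometastatic replicate 1, 18 rose, all of them among the 19, and 1 fell. These miRNAs were chosen by that test, after their values were seen.

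Means of the fixed lists were set against the same signal in 19 relations, with exact permutation over all 40320 orders. After adjustment 3 passed by Pearson's r and 0 by Spearman's rho. The primate X-linked cluster had r = 0.905 (permutation p = 0.00315, adjusted p = 0.0199) and rho = 0.786 (permutation p = 0.0279, adjusted p = 0.137). miR-204 had r = 0.937 (permutation p = 0.00119, adjusted p = 0.0199) and rho = 0.738 (permutation p = 0.0458, adjusted p = 0.137). The list reputed to promote metastasis had r = 0.935 (permutation p = 0.00221, adjusted p = 0.0199) and rho = 0.810 (permutation p = 0.0218, adjusted p = 0.137). Without oligometastatic replicates 2 and 4, the samples farthest from the median signal, r was 0.855, 0.893 and 0.832, and without oligometastatic replicate 1 it was 0.953, 0.929 and 0.950. These relations in part repeat the limma fit and are no separate support. miR-204 is a single miRNA and was among the 19 that rose, as were miR-508-3p and miR-509-5p of the primate cluster. The list reputed to promote metastasis holds miR-155 and miR-182, which rise with the signal by themselves. Of the lists that did not pass, the miR-17 cluster and its paralogs had r = 0.820 (permutation p = 0.0126, adjusted p = 0.060) and rho = 0.714 (permutation p = 0.0576, adjusted p = 0.137), and r = 0.823 without the same 2 samples. The miR-200 family had r = -0.817 (permutation p = 0.0170, adjusted p = 0.0647) and rho = -0.714 (permutation p = 0.0576, adjusted p = 0.137), and r = -0.978 without the same 2 samples. The endothelium list had r = -0.782 (permutation p = 0.0232, adjusted p = 0.0736) and rho = -0.643 (permutation p = 0.0962, adjusted p = 0.166).

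A candidate explanation of this pattern is the amount of human tumour RNA in each extract. It needs miRNAs of the primate cluster to gain on host miRNAs as the signal rises, and the slope of that cluster minus the slope of the smooth muscle and fibroblast list was 0.708 ± 0.144 per cycle (SE). This leaves the explanation open, since 2 of the 3 cluster members and 1 smooth muscle miRNA were already among the miRNAs picked for following the signal. Of cluster members not tested, miR-509-3-5p was detected in oligometastatic replicate 1 (Ct 30.5) and polymetastatic replicates 2 (32.6) and 4 (34.2). It was at 36.5 in polymetastatic replicate 1, which had the highest signal. That rank rests on MammU6, whose Ct of 19.4 there was the highest of all cards. RNU44 and RNU48, at 26.9 and 25.4, had higher Ct values there than in oligometastatic replicate 1 and polymetastatic replicates 2 and 4. miR-510 was detected in replicate 1 of each group, at Ct 33.8 and 34.3, and miR-508-5p in oligometastatic replicate 1 only. From the other primate cluster, miR-518f did not follow the signal. It was detected only in oligometastatic replicates 3 and 4, near the limit, and replicate 4 had the lowest signal of all samples. miR-211, not tested, ran in the order of the signal among oligometastatic lungs, at Ct 28.7 in replicate 1, 32.2 in replicate 3 and undetermined in replicates 2 and 4. It did not in polymetastatic lungs, where it was undetermined in replicates 1 and 4 and at Ct 36.7 in replicate 2, which have high signals, and at 38.4 in replicate 3. Of 100 orders of the signal, only the real 1 gave as many miRNAs, 23 in all, and the highest of the others gave 6. Chance is not excluded by this, since the relation was chosen after the values were seen. The miRNAs also vary together, with 77.7% of the variance on 1 principal component. More total template or a more sensitive card would lower the mean Ct as the signal rises, whereas the mean Ct of assays detected on all cards had a slope of 0.0334 ± 0.0373 cycles per cycle of signal (SE). The Ct of the rising miRNAs had a median slope of -0.575. They were picked for a Ct that falls against that mean, so the contrast between these slopes decides nothing. Whether the tumour cells themselves express more of these miRNAs in some lungs stays open, as the cards do not separate the species.

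For the comparison of the groups, the 35 splits of the 8 samples into 4 and 4 decide nothing about chance, since all 35 must give at least the real count of 0 miRNAs and 0 lists. The highest of the other splits gave 49 miRNAs and 6 lists, far above the real count, and all the rest of the splits gave 0 miRNAs. It sets oligometastatic replicate 1 with polymetastatic replicates 1, 2 and 4, the 4 samples with the highest human snoRNA signal, and equals an exchange of oligometastatic replicate 1 with polymetastatic replicate 3. This split was singled out as the highest after all had been run, so its count is no test of a structure other than the labelled groups.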
